A study of Mus musculus with 2 samples.

How the data were processed

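A pair of stable lines of a mouse embryonic stem cell line was profiled on an Affymetrix whole-transcript expression array, with 1 sample for each line. Per the labels' protocols, both lines were grown in embryonic stem cell medium with LIF and received doxycycline at 1 µg/ml to lower the endogenous OCT-4. The length of the treatment is not given in the sources used here. Total RNA was isolated with Trizol, amplified with random primers through cRNA, copied back to cDNA, fragmented and labelled with biotin, per the labels' protocols.

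The authors deposited 1 table of values with a row for each of 33793 probe sets and a column for each of the 2 samples. Per the submitters' processing notes the values are RMA summaries made with Affymetrix Expression Console 1.1. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set by median polish. The deposited values were taken as log2 because RMA gives log2 values and they ran from 0.618 to 13.0, but the table itself does not state the log base. Quantile normalization forces the arrays onto a common distribution, so a shift of most transcripts in the same direction would not be visible. RMA also compresses differences of weakly expressed genes, and no detection call was used here, so how far a low value lies above background is unknown. The series' design text says that experiments were duplicated, whereas each line has 1 column. Whether a column is 1 array or the mean of duplicate arrays is not given in the sources used here. The number of arrays limits the precision, and no error can be attached to any single value.

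Probe sets were named from the platform annotation. Of the 33793 probe sets, 23521 had 1 gene symbol, 1814 had several and 8458 had none in that table. Symbols were looked up by gene ID in a RefSeq table of assembly GRCm38.p6, which held 23328 of the single-symbol probe sets, and 0 symbols differed. Because the build behind the array annotation is not given in the sources used here, no coordinates are reported. The 23521 single-symbol probe sets named 22180 genes. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over both arrays stood for the gene.

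The comparison is the EWS-OCT4A-GFP value minus the GFP control value on the log2 scale. With 1 sample per group no test of the conditions is possible, and no p-value is given. Genes and probe sets were described by size instead: a log2 difference of at least 1 (2-fold) in either direction, with the higher value of the pair at or above 4.10, the median of all values on both arrays. To say whether a gene list stood apart, the median difference of the list was placed among the medians of 10000 random gene lists of the same size, matched on mean level in 20 bins. A list is said to stand apart when its median lay outside the middle 95% of the random medians. That percentile describes these 2 samples and does not test the conditions.

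The 23 gene lists, the floor, the size threshold, the rule for named genes and the alternatives were fixed before the data were examined, unless stated otherwise. The lists were drawn up from general knowledge and held 441 entries, of which 52 had no probe set of their own and were not analysed here. The rule named Pou5f1, Ewsr1, Fgf4 and Sox2, then the 15 genes with the largest positive and the 15 with the largest negative difference, and up to 4 members of each list with the largest absolute difference, all at or above the floor. Symbols of predicted or uncharacterised models, olfactory and vomeronasal receptors, receptor segments and small RNAs were left out of that ranking. They numbered 1337 of the 13516 genes at or above the floor, and 151 of them were at least 2-fold higher and 72 at least 2-fold lower in the EWS-OCT4A-GFP sample. Other genes named in the text were chosen after their values were seen.

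Alternatives covered the size threshold (1.5-fold and 3-fold), the floor (none, the 75th percentile, a log2 value of 6), the normalization (median centring, quantile normalization, loess of the difference on the mean level with a span of 0.3), the unit counted, the rule for several probe sets and the matching of random lists. Leaving out members that stand on more than 1 list was added after seeing the data. The procedure was tested on simulated data for this comparison, with 22180 genes of which 200 were changed. The simulated noise was normal and narrower than the spread of the real differences, and changed genes were drawn only from well above the floor. The rates that follow depend on these settings and are not error rates of the real comparison. Of 100 genes changed by a log2 value of 2.0, 100% were called, and of 100 changed by 1.5, 92.0% were called, whereas 0.323% of the unchanged genes were called. Of 200 simulated lists without changed members, 3.0% stood apart, and of 50 lists in which 8 of 20 members were changed, 82.0% did. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.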

Results

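Transcript levels were measured in 2 samples of mouse embryonic stem cells, 1 of a stable line expressing EWS-OCT4A-GFP and 1 of a control line expressing GFP. EWS-OCT4A joins the EWS protein, encoded by EWSR1 in human, to OCT4A, the pluripotency isoform of the POU transcription factor encoded by POU5F1. Fusions of these 2 genes occur in some human tumours. Both lines were treated with doxycycline at 1 µg/ml, which lowers the endogenous OCT-4 of this cell line. The comparison asks which genes differ between cells with and without the fusion when endogenous OCT4 is lowered, and the title of the series names Fgf4 as its target. Each group has 1 sample, so none of the differences has a replicate check. No sample without doxycycline was included. A difference therefore cannot be split into a change in the EWS-OCT4A-GFP line and a change in the control line, here and below. The deposited log2 values had medians of 4.11 in the EWS-OCT4A-GFP sample and 4.08 in the GFP control, and the 2 samples correlated with r = 0.935 across 33793 probe sets, which are not independent replicates.

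The genes that make up the fusion and are measured on the mouse array differed little. Pou5f1 (probe set 17337155) read 5.37 in the EWS-OCT4A-GFP sample and 5.24 in the GFP control, a log2 difference of 0.13. Ewsr1 (probe set 17260089) read 8.46 and 8.35, a difference of 0.11. Whether these probe sets detect the transgene is not given in the sources used here, so neither value checks the labels of the samples. Fgf4 (probe set 17485437), which encodes an FGF ligand secreted by embryonic stem cells, read 8.38 in the EWS-OCT4A-GFP sample and 4.09 in the GFP control. Its difference was 4.29. The control value lay just under the floor of 4.10, and with the control set to that floor the difference was 19.4-fold. Background is unknown for values near the floor, so the size of a difference with 1 value under it is uncertain, here and below. Sox2, which encodes the partner of OCT4 at the Fgf4 enhancer, read 9.87 and 5.50, a difference of 4.37 or 20.7-fold.

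Across the array, 1696 probe sets were at least 2-fold higher and 1936 at least 2-fold lower in the EWS-OCT4A-GFP sample, of 18255 at or above the floor. These shares were 9.29% and 10.6%. A difference of at least 16-fold was seen for 29 probe sets in the higher direction and 68 in the lower. The counts are sizes in 2 samples and carry no error estimate. With a 3-fold threshold they were 611 and 937, and with a 1.5-fold threshold 3784 and 3453. With the floor raised to a log2 value of 6, 1126 probe sets were higher.

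**Figure D1:**
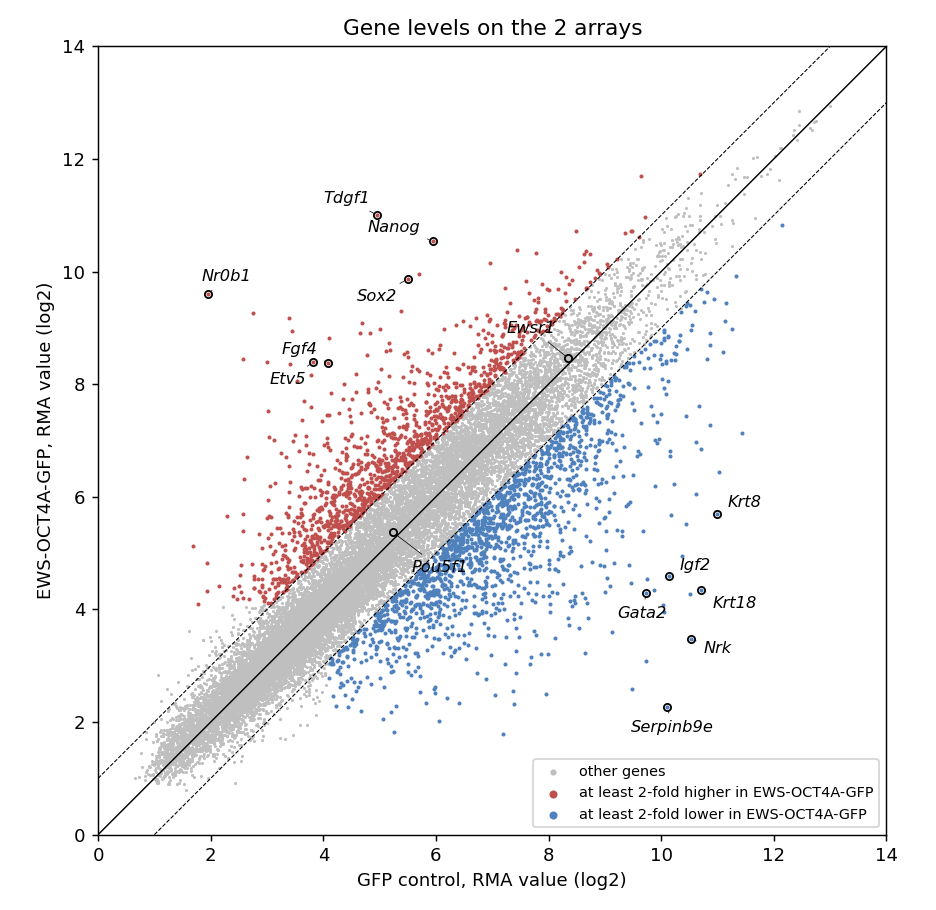
RMA value (log2) of each gene in the GFP control (horizontal axis) and in the EWS-OCT4A-GFP sample (vertical axis), with 1 point per gene. The solid line marks equal values and the dashed lines a 2-fold difference; Nr0b1, Tdgf1, Nanog, Sox2, Fgf4 and Etv5 lie far above the line, Krt18, Krt8, Gata2, Igf2, Nrk and Serpinb9e far below it, and Pou5f1 and Ewsr1 on it.

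The largest positive difference was that of Nr0b1, which encodes the orphan nuclear receptor DAX1, with 9.60 in the EWS-OCT4A-GFP sample and 1.96 in the GFP control, a log2 difference of 7.65. It was followed by Pla2g1b, a secreted phospholipase, with a difference of 6.51, and Tdgf1, which encodes the Nodal co-receptor Cripto, with 6.04. Lrrc34 was higher by 5.88, Jam2, a junctional adhesion molecule, by 5.79, and Slc7a3, a cationic amino acid transporter, by 5.50. Apela, which encodes a peptide ligand of the apelin receptor, was higher by 5.40, Trh by 4.94 and Pipox by 4.72. Nanog, a core pluripotency transcription factor, was higher by 4.61 and the TGF-beta family ligand Gdf3 by 4.53. Etv5, an ETS factor induced by FGF signalling, was higher by 4.57. Sohlh2 was higher by 4.39 and Socs2 by 4.38. Sox2 completed the 15 genes, of which 5 were on the list of pluripotency factors.

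The largest negative difference was that of Serpinb9e, a serine protease inhibitor from a cluster of similar genes, with 2.27 in the EWS-OCT4A-GFP sample and 10.1 in the GFP control, a log2 difference of -7.84. The probes of a gene with near-identical copies can be shared, so this value is uncertain as to the member. Nrk, a kinase of placental trophoblast, was lower by a difference of -7.04 (10.5 in the control). Olr1 differed by -6.88 and Nxf7 by -6.65. Krt18, an epithelial keratin, differed by -6.37, Syna, which encodes the placental fusion protein syncytin-A, by -6.25, and Zfp36l3, a placental RNA-binding protein, by -6.11. The connexin gene Gjb2 differed by -5.96, the growth factor Igf2 by -5.54, App by -5.54, Dkkl1 by -5.52, Vnn1 by -5.45, the trophoblast transcription factor Gata2 by -5.45, Ndrg1 by -5.43 and Arhgef6 by -5.41. Krt18 and Gata2 were the 2 genes of the 15 that were on the list of trophectoderm markers.

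Pluripotency factors were higher in the EWS-OCT4A-GFP sample. All 30 measured members of the list had a difference above 0, 25 of them by at least 2-fold, and none was 2-fold lower. The median difference was 1.89, above all 10000 random lists of the same size, whose middle 95% ran from -0.29 to 0.32. Nr0b1, Tdgf1, Nanog and Gdf3 differed most. The naive-state factors Esrrb (7.05 against 4.07) and Klf2 (8.30 against 6.18) were also higher. Members that stayed within 2-fold included Klf5 (0.25), Sall4 (0.82) and Lin28a (0.39). Of the 9 measured genes listed for a composite OCT4-SOX2 site, 7 were at least 2-fold higher, with a median of 1.90. Nanog, Sox2, Fgf4 and Zscan10 (2.98) differed most. This list shares 7 members with the pluripotency list, so it is not separate evidence. Without members on another list only Pou5f1 (0.13) was left.

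Trophectoderm markers were lower in the EWS-OCT4A-GFP sample. All 27 measured members had a difference below 0, 23 of them by at least 2-fold, and the median was -3.12, below all 10000 random lists (middle 95% from -0.30 to 0.33). Krt18, Gata2, Krt8 (-5.29) and Cldn4 (-4.50) differed most. The 4 members within 2-fold were Cdx2 (a difference of -0.55), the transcription factor that specifies trophectoderm, Tead4 (-0.30), which acts upstream of it, Elf5 and Tpbpa. Imprinted genes, several of which are abundant in placenta, were also lower, with a median of -0.93, below all 10000 random lists. Of the 18 measured, 9 were at least 2-fold lower and 2 at least 2-fold higher. Igf2, Peg10 (-4.31), Peg3 (-3.85) and the cell cycle inhibitor gene Cdkn1c (-2.71) differed most.

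**Figure D2:**
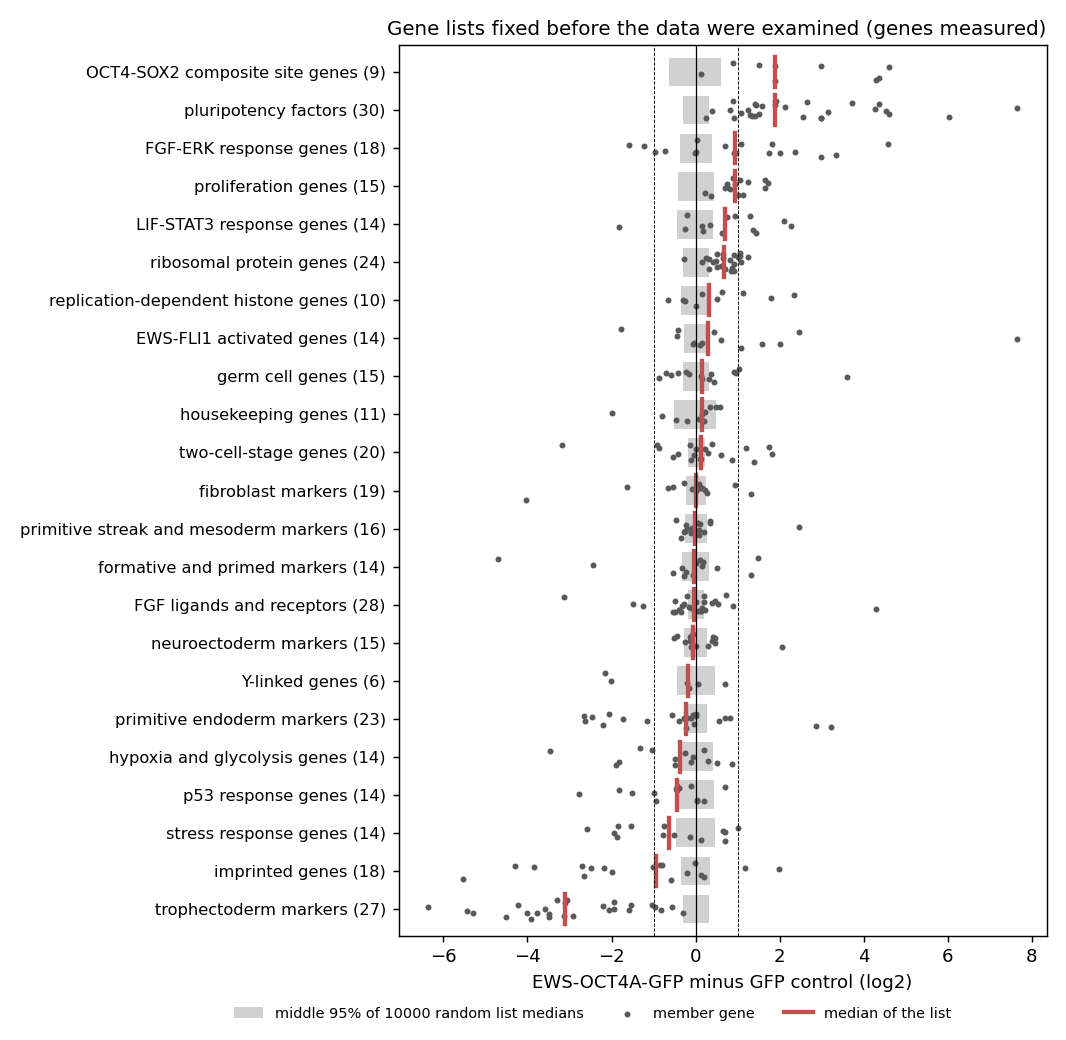
Difference between the samples (EWS-OCT4A-GFP minus GFP control, log2) for each measured member of the 23 gene lists (points), with the list's median (red bar) and the middle 95% of the medians of 10000 random lists matched on level (grey). Pluripotency factors (median 1.89) and trophectoderm markers (median -3.12) lie on opposite sides, outside the grey bands.

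Markers of other lineages did not stand apart as lists over all measured members against level-matched random lists, though some did under the alternatives given here. Primitive endoderm markers had a median of -0.23, at percentile 3.25 of the random lists, with 7 of 23 members at least 2-fold lower and 2 higher. Over its 17 members at or above the floor the median was -0.38, at percentile 2.34, which stands apart, as did all 23 members (percentile 2.15) against random lists not matched on level. Dab2 differed by -2.65 and Col4a1 by -2.62, whereas Apoe (3.23) and Lama1 (2.86) were higher. Primitive streak and mesoderm markers had a median of -0.01 (0.07 over members at or above the floor), and 15 of 16 stayed within 2-fold. The exception was Nodal, a TGF-beta family ligand, which read 6.79 and 4.33. Snai1 (-0.46), Tbx6 (-0.34) and Msgn1 (0.34) were within 2-fold. Apart from Nodal, the highest reading of a member was 5.50 (Foxf1, GFP control). Differences among such low values can be compressed, so they do not show equal levels. Tbxt had no probe set of its own. Neuroectoderm markers had a median of -0.06, which turned to 0.29 (percentile 90.7) over members at or above the floor, and only Stmn2 (2.06) of 15 exceeded 2-fold, with Nes at -0.52, Map2 at 0.46 and Pax6 at 0.46. Low values limit this list too, with Pax6 at 4.75 in the EWS-OCT4A-GFP sample and 4.30 in the GFP control. Formative and primed markers had a median of -0.04, with Dnmt3l (1.49) and Otx2 (1.31) higher and Car4 (-4.69) and Cldn6 (-2.44) lower by at least 2-fold. Germ cell genes had a median of 0.15 (0.37 at or above the floor, percentile 90.8), with Rpl10l (3.60), Dazl (1.03), Stk31 (0.97) and Mov10l1 (0.91) differing most. Genes of the 2-cell stage had a median of 0.12 (percentile 81.3), but one of 0.71 (percentile 99.5) over the 8 at or above the floor, with Zscan4e (1.83), Zscan4d (1.74) and Zscan4c (1.38) higher and Tdpoz2 (-3.18) lower. The Zscan4 and Tdpoz genes are families of near-identical copies, so the member is uncertain. Zscan4 genes made up most of the 8, and the random lists counted each as a separate gene, so the percentile of 99.5 is uncertain too. Fibroblast markers, which would report feeder cells, had a median of 0.02 (-0.02 under loess centring), although Postn (-4.04) and Acta2 (-1.64) were lower and Fn1 (1.33) higher. Mmp2 differed by 0.94.

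FGF ligands and receptors as a list did not stand apart (median -0.05, percentile 26.2, and 0.12 over members at or above the floor), with 14 of 28 members above 0 and 14 below, and 24 stayed within 2-fold. Fgf4 was the 1 member at least 2-fold higher. The receptor gene Fgfr2, also a trophectoderm marker, read 4.88 in the EWS-OCT4A-GFP sample and 8.01 in the GFP control, a difference of -3.12. Fgfrl1 differed by -1.49 and Fgfbp1 by -1.24. Genes of the FGF-ERK response were higher, with a median of 0.94 against a random middle 95% of -0.38 to 0.39, above all 10000 random lists. Of 18 members, 8 were at least 2-fold higher and 2 at least 2-fold lower. Etv5, Spred1 (3.34), the ERK phosphatase gene Dusp6 (2.98) and the feedback inhibitor gene Spry4 (2.38) differed most. The 2 members lower by at least 2-fold were Dusp5 (-1.58) and Fos (-1.22), and Egr1 was level at -0.02. Genes of the LIF-STAT3 response had a median of 0.69, at percentile 99.94. The LIF receptor gene Lifr (2.28), Icam1 (2.10) and Klf4 (1.43) were higher and Osmr (-1.83) lower. Socs3, the feedback inhibitor of STAT3, differed by 0.94.

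Genes of cell proliferation were higher. All 15 had a difference above 0 and 7 reached 2-fold, with a median of 0.93, above all 10000 random lists. The replication genes Mcm3 (1.72), Pcna (1.66) and Mcm6 (1.65) and the cyclin gene Ccne1 (1.24) differed most. Ribosomal protein genes were higher in 23 of 24 cases with a median of 0.68, also above all 10000 random lists, although only 5 reached 2-fold. Rps18 (1.25), Rpl6 (1.07), Rpl7 (1.07) and Rpl37 (1.06) led the list, and probes of these genes can be shared with processed pseudogenes. Genes of the p53 response had a median of -0.45 (percentile 2.09), with 3 of 14 at least 2-fold lower. Cdkn1a, which encodes the cell cycle inhibitor p21, read 6.81 and 9.59, a difference of -2.77. Btg2 (-1.82), Sesn1 (5.12 against 6.62) and Polk (6.18 against 7.18) followed. With members at or above the floor only, this list lay at percentile 4.08 and no longer stood apart. Stress response genes had a median of -0.63 (percentile 0.74), with 5 of 14 lower by at least 2-fold. The heme oxygenase gene Hmox1 (-2.59), Gadd45b (-1.94), the heat shock gene Hspa1a (-1.87) and Atf3 (-1.85) differed most, and Asns (1.01) was the 1 member higher by at least 2-fold.

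Hypoxia and glycolysis genes had a median of -0.37 (percentile 3.92) and did not stand apart. The list stood apart against random lists not matched on level (percentile 0.73) and without its member shared with another list (1.94), whereas averaging probe sets gave a median of -0.22 (percentile 10.8). Bnip3 (-3.47), Egln3 (-1.89), Vegfa (-1.81) and the glucose transporter gene Slc2a1 (-1.32) were lower. Genes known to be activated by the related tumour fusion EWS-FLI1 had a median of 0.30 (percentile 97.2). Over members at or above the floor the median was 1.08 (percentile 99.98) and the list stood apart, as it did under loess centring (97.84), whereas without members on another list the median was 0.13 (percentile 79.7). Nr0b1, Gli1 (2.46) and Ccnd1 (2.01) were higher and Id2 (-1.77) lower. Nr0b1 is also on the pluripotency list and Ccnd1 on that of the FGF-ERK response. Replication-dependent histone genes had a median of 0.32 (percentile 96.1, 10 measured) and of 0.64 (percentile 93.7) over those at or above the floor, with H1f5 (2.35), H2bc12 (1.78), H2ac20 (0.64) and H2bc3 (0.50) differing most among genes at or above the floor. Y-linked genes had a median of -0.18 over 6 genes (percentile 18.1), but one of -2.01 (percentile 0.49) over the 3 genes at or above the floor. Eif2s3y (-2.16) and Uty (-2.01) were lower and Uba1y differed by 0.06. Housekeeping genes had a median of 0.15 (percentile 66.6; 0.05 under loess centring), and 10 of 11 stayed within 2-fold, among them Actb (-0.80), Tbp (0.59) and Tubb5 (0.48). The exception was B2m, which encodes the light chain of MHC class I molecules, at -1.98.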

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

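With 1 sample per group, no replicate could be left out and no paired analysis was possible because each group holds a single sample. Counts of probe sets at least 2-fold higher and lower (1696 and 1936) became 3784 and 3453 at 1.5-fold and 611 and 937 at 3-fold, and 1126 were higher with the floor at a log2 value of 6. Median centring (1581 and 2027), quantile normalization (1699 and 1922) and loess centring (1474 and 2155) kept the counts within 1.5 times. The largest move of any list median under these 3 normalizations was 0.13. All 30 genes of the 2 rankings kept their direction and 2-fold size under loess centring, and all 30 were still named with the floor at the 75th percentile. Neither check could well have failed. The 30 genes differed by at least 4.37 in size, and the higher value of each was at least 7.19, above that floor of 5.80. With members at or above the floor only, the medians moved to -0.38 for primitive endoderm, 0.29 for neuroectoderm, 0.12 for FGF ligands and receptors, 0.71 for 2-cell-stage, 0.37 for germ cell, 1.08 for EWS-FLI1 activated, 0.64 for histone and -2.01 for Y-linked genes; by construction these use fewer genes. In that setting the primitive endoderm, 2-cell-stage, EWS-FLI1 and Y-linked lists stood apart and the p53 list did not. Averaging the probe sets of a gene gave -0.22 for the hypoxia list, at percentile 10.8. With random lists not matched on level the primitive endoderm (percentile 2.15) and hypoxia (0.73) lists also stood apart, as did the EWS-FLI1 list under loess centring (97.84). Without members on more than 1 list, chosen after seeing the data, the EWS-FLI1 list had a median of 0.13 and the OCT4-SOX2 list, reduced to Pou5f1 alone, 0.13, while the hypoxia list stood apart at percentile 1.94. The pluripotency, trophectoderm, FGF-ERK, LIF-STAT3, stress, proliferation, imprinted and ribosomal protein lists stood apart under every alternative run. Signal over background is unknown for these values, which limits what can be said of genes near the floor.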

Other observations

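The tests of fibroblast RNA, of swapped labels and of a difference between the lines were chosen after the results were seen. So were the grouping of genes by symbol root, the comparison of chromosomes and the random orders of chromosome 1 genes. The marks of the chromosome tests were fixed before those tests were run, but those for chromosome 1 concerned a chromosome already singled out. The other tests were fixed before their results were seen.

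Genes were grouped by the root of their symbol, and 204 roots with at least 8 genes at or above the floor were compared with random lists as above. Of these, 13 stood apart as higher and 24 as lower in the EWS-OCT4A-GFP sample, against about 10.2 expected by chance in all. That expectation treats the genes of a root as independent. Members of a family can share probes or regulation, so the excess is not a test. The roots Rpl, Rps, Mcm and Zscan, which were among the higher ones, also share genes with the lists above. Zinc finger genes with symbols beginning Zfp were higher, with a median of 0.42 over 317 genes, of which 64 were at least 2-fold higher and 10 at least 2-fold lower. Zfp57, which maintains methylation at imprinted regions, read 9.29 in the EWS-OCT4A-GFP sample and 5.38 in the GFP control. The Platr genes, noncoding transcripts named for their association with pluripotency, had a median of 1.82 over 13 genes, 8 of them at least 2-fold higher, with Platr10 (4.03) and Platr7 (3.52) in the lead. Small nucleolar RNA host genes (Snhg) had a median of 1.20 over 13 genes and RNA polymerase subunit genes (Polr) one of 0.49 over 25, of which 23 were within 2-fold.

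Annexin genes (Anxa) were lower, with a median of -2.96 over 10 genes and 7 at least 2-fold lower, among them Anxa1 (-4.79) and Anxa5 (-4.47). Serpinb genes had a median of -2.14 over 12, with 7 at least 2-fold lower and 1 at least 2-fold higher, in a family with near-identical members. Solute carriers (Slc) had a median of -0.13 over 247 genes, with 52 at least 2-fold lower and 18 at least 2-fold higher. Oxysterol-binding protein genes (Osbpl) had a median of -1.04 over 10, with 6 at least 2-fold lower and 1 at least 2-fold higher. Phosphatase genes with symbols beginning Dusp had a median of -0.70 over 19, with 6 at least 2-fold lower. At least 2-fold higher were 2 of them, among them Dusp6 (2.98) of the FGF-ERK response list. Sorting nexins (Snx, -0.43) and syntaxins (Stx, -0.62) were lower by smaller amounts, with 24 of 30 and 10 of 13 within 2-fold. Outside these groups, Dppa1 was lower (2.31 against 7.39) although Dppa2 (1.09) and Dppa4 (1.90) were higher, and the 5-methylcytosine oxidase gene Tet1 was higher (9.95 against 5.70).

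The opposite position of the pluripotency and trophectoderm lists is the main pattern. Without a sample free of doxycycline, it cannot be said in which of the 2 lines these genes changed. After loess centring the smaller of the 2 absolute list medians was still 1.80. That step decides little, because the values were already quantile-normalized and loess moved no list median by more than 0.13. Random lists matched on level had medians of only 0.035 (pluripotency) and 0.024 (trophectoderm). These argue against a level-dependent bias shared by genes of the same level. Fibroblast RNA in 1 sample was argued against for the lists as a whole, because the collagen genes Col1a1, Col1a2 and Col3a1, abundant in fibroblasts, read only 4.09 to 5.01 and differed by at most 0.28, although Postn (-4.04) and Acta2 (-1.64) of the same list were lower in the EWS-OCT4A-GFP sample. Swapped labels cannot be told apart from the labels as given, since Pou5f1 differed by 0.13, and the higher Fgf4 in the array labelled EWS-OCT4A-GFP is the outcome under study, not a reading of the transgene. A difference between the 2 stable lines that does not come from the fusion stays open too, with 1 line per group, as does the effect of the fusion itself, which was not tested. Of 5 genes of chromosome Y at or above the floor, listed or not, Eif2s3y (-2.16) and Uty (-2.01) were lower in the EWS-OCT4A-GFP sample. The rest stayed within 2-fold, and the reason was not tested.

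Ribosomal protein genes were higher in 23 of 24 cases, with differences from -0.28 (Rps16) to 1.25 (Rps18). Rps16 read 3.42 in the EWS-OCT4A-GFP sample and 3.70 in the GFP control, both under the floor, so its direction is uncertain. Random lists matched on level had a median of 0.035 against 0.68 for this list, which argues against a level-dependent normalization bias as the whole cause. The list stayed at percentile 99.99 after loess centring, but that adds nothing, because matching on level already cancels such a bias. With 23 of 24 members above 0, the direction of the list did not rest on a few members. Without the 5 largest differences the remaining 19 genes had a median of 0.61 and percentile 99.96. That check adds little, because a median depends little on its largest values. A higher growth rate of the cells in the EWS-OCT4A-GFP sample may accompany this, given the proliferation list, but it was not tested, and probes shared with pseudogenes stay open.

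Chromosomes were compared through the median difference of their well expressed genes (7906 genes at or above the 75th percentile, assigned by assembly GRCm38.p6). Chromosome Y had too few such genes to be compared. Chromosome 1 had a median of 0.31 over 473 genes, 0.27 above that of all genes and above all 10000 random lists, while chromosome 13 (0.11 above, percentile 98.1) and chromosome X (0.15 below, percentile 1.56) also lay outside the middle 95%. The offset of chromosome 1 fell short of the 0.3 set in advance for a gain or loss of a whole chromosome. It was also too large for the mark set in advance against one, so that test decided nothing. Of its 10 blocks of neighbouring genes, 7 lay over 0.15 above the median of all genes. This met 1 of the 2 marks set in advance for a gain of chromosome 1 or of a large part of it, either of which was to be enough. The other mark, 3 adjacent blocks over 0.3 above that median, was not met, and blocks 7 to 9 lay from -0.07 to -0.02. Only chromosomes 14 and X had 3 adjacent blocks over 0.3 away, in both cases below. The count of 7 blocks decides nothing, because 96.7% of 10000 random orders of the same chromosome 1 genes also reached 7 blocks. The 307 chromosome 1 genes within 2-fold had a median of 0.225 and lay at percentile 99.99. All well expressed genes within 2-fold had a median of 0.081. These values argue against a minority of genes that differ at least 2-fold as the whole cause of the offset. The filter rests on the difference itself, so the size of the remaining offset is uncertain. Whether chromosome 1 or a large part of it was gained stays open.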
